A study of Mus musculus with 4 samples.

How the data were processed

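Samples were 2 multiome libraries read as 4 libraries in all, RNA and ATAC for alloBMT and for PT-Cy, each from a pool of 4 mice taken on day 14, so groups hold 1 library each. Group assignment followed the labels. Per the submitters' processing notes the tools were Cell Ranger ARC 1.0.1 and MACS2, whose version and settings are not given in the sources used here. Those notes name the build GRCh38, a human build; the gene names are mouse, and the deposited peaks were checked against the mouse assembly GRCm38.p6, where 32.1% of 41310 ends of protein-coding genes lay in a peak, against 6.28% to 7.01% when the ends were shifted by 2000 to 200000 bases. Peak positions are printed as deposited and that gene table was used only for which gene a peak overlaps or lies near.

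The deposited RNA and ATAC tables hold whole-number counts per gene or peak and cell, with no normalization, per the file headers and the values, and the cells had been filtered by the authors in a way not given in the sources used here. The lowest totals per cell were 1017 UMIs and 1003 ATAC counts, and the highest mitochondrial share was 10.0%. The deposited per-cell table gives counts per cell, the mitochondrial percent, the fraction of fragments in peaks, the TSS enrichment ratio and module scores, per the file headers. The deposited fraction in peaks had a median, given here as a percent, of 66.6% in alloBMT and 58.3% in PT-Cy CD4 cells. The ratio of TSS enrichment deposited by the authors had medians of 5.44 and 5.27. The gene sets behind the deposited scores are not given in the sources used here. That per-cell file has 58 columns, of which 38 were not used. Doublet treatment by the authors is not given in the sources used here; no doublet caller was run, and results were recomputed without the 5% of cells with the most UMIs.

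Counts were summed over the cells of each library and set, scaled to a common total per set (CPM), and compared as log2 ratios of PT-Cy to alloBMT, with the exact conditional binomial (Clopper-Pearson) 95% interval. Cells are not replicates, so no test was run. Intervals cover counting error only. A size rule of 2-fold with at least 100 counts over both libraries was fixed before the data were examined, as were 25 gene lists with 422 genes, for T cell states, stress, metabolism and other blood cells. List members needed at least 20 counts. A count of 0 was set to a floor of 3 counts where the other library had more than that. Each list's median was placed among medians of 10000 random lists of equal size, matched in 20 bins of mean level. Named genes were, by a rule fixed at the same time, the 12 with the highest lower bound and the 12 with the lowest upper bound of the interval, leaving out receptor segments, ribosomal, mitochondrial, haemoglobin, sex-linked and predicted genes, up to 4 members of each list with at least 100 UMIs and the largest absolute ratio, a fixed set of lineage and state genes, the 5 leading genes of a cluster, and 5 peaks in each direction. Some genes that the rule names are not reported here. The shorter sets planned within each T cell class were replaced by those 12, because the RNA counts cover 1 class. Lag3, Nr4a2, Ccr7 and Il2ra were added at the ATAC level after their RNA values were seen. Thinning took each cell to the 10th percentile of UMIs, by drawing without replacement, with shares given exact binomial intervals.

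Accessibility at a gene was the sum of counts of peaks overlapping the gene or within 2 kb of it, for 17161 genes. The plan named windows around transcription start sites, but the gene table used has no strand, so the whole gene was taken. Motif analysis needs a genome sequence and was not run. Equal weighting of CD4 and CD8 RNA and RNA within the CD8 set were not run, because the RNA counts used here cover the CD4 set.

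The computation was tested on simulated counts with the real library sizes, drawn independently (Poisson) per library, which leaves out the spread between cells. With 6240 RNA genes the interval held the true value in 95.4% of the unchanged ones. Of 190 genes changed by a log2 ratio of 1.5, 97.4% passed 2-fold. With 44697 peaks these were 95.8% of the unchanged ones, and 97.0% of 197 changed ones. Coverage was not computed for changed genes or peaks. The limit on the width of intervals in the test of free RNA, the requirement that a counting interval lie past a predicted bound, and the rule that the test without Cd8b1 UMIs decides only if it removes most of the CD8 accessibility of both libraries, were set after values were seen. Alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, other count minimums, per-cell means, other cell subsets, other depths of thinning, binary peak counts, a 10 kb window, and equal weights of both sets for peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.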

Results

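T cells were taken from the bone marrow of mice 14 days after an allogeneic bone marrow transplant, in which C57BL/6 recipients received 5000000 marrow cells with 500000 CD4 and 500000 CD8 T cells from C3H.SW donors. One group received the transplant alone (alloBMT). The other also received 50 mg/kg cyclophosphamide, a drug that kills dividing cells, on days 3 and 4 after the transplant (PT-Cy). CD4 and CD8 T cells were sorted from a pool of 4 mice per group, and RNA and open chromatin (ATAC) were read from the same nuclei, which gave 4 libraries, 1 per group and assay. With 1 library per group there is no replicate check on any difference, no test was made and no p-value is given. The intervals printed are exact 95% intervals that cover counting error only, not the spread between mice. Those of count ratios also leave out the spread between cells.

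The authors' table of cells holds 926 CD4 and 1865 CD8 cells of the alloBMT group and 284 CD4 and 512 CD8 cells of the PT-Cy group. The CD4 set made up 33.2% of alloBMT cells (31.4 to 35.0) and 35.7% of PT-Cy cells (32.3 to 39.1), shares that the sort and the authors' assignment of cells can set. The RNA counts used here cover the CD4 set, with 3027967 UMIs (unique molecules) in alloBMT and 1264107 in PT-Cy, a median of 2750 and 3889 UMIs per cell. The ATAC counts cover both sets, with 23580292 counts in peaks in alloBMT and 4656839 in PT-Cy, and here the PT-Cy cells were the shallower ones, with a median of 4090.5 against 6874 counts per CD4 cell. RNA of the CD8 set was not analysed here.

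The CD4 set carried some signal of CD8 cells, with higher values in PT-Cy, though some of their intervals overlap. Every cell of the set had a Cd4 UMI and none had a Cd8a UMI, so these 2 genes reflect how the set was chosen. A UMI of Cd8b1, the other chain of the CD8 co-receptor, was found in 21.1% of alloBMT cells (18.5 to 23.8) and 32.0% of PT-Cy cells (26.7 to 37.8), and after thinning every cell to 1981 UMIs in 15.9% of alloBMT cells (13.5 to 18.6) and in 57 of 259 PT-Cy cells (17.1 to 27.6%). Accessibility at Cd8a and Cd8b1 in the CD4 set stood at 21.3% of the level of the CD8 set in alloBMT and 32.5% in PT-Cy. Transcripts of other blood cells were also higher in PT-Cy: Hbb-bs, a haemoglobin chain of red cells, had 112 CPM (counts scaled to a common library total) in alloBMT and 471 in PT-Cy, and S100a9, a neutrophil protein, 13.2 and 71.2.

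The first question the design puts is how T cells in the marrow differ after PT-Cy. Of 6285 genes with at least 100 UMIs over both libraries, 310 were at least 2-fold higher and 181 at least 2-fold lower in the PT-Cy CD4 library. With edgeR's TMM scaling, which shifts all log2 ratios down by 0.13, the split was 234 higher and 260 lower. In a simulation of this comparison with 6240 genes, 0 unchanged genes passed 2-fold by counting error. Its counts were drawn independently, which leaves out the spread between cells. The genes with the highest lower bounds included Coro2a at 10 UMIs against 99 (log2 ratio 4.57, 3.63 to 5.67), Adam12 (4.19), Dscam (3.28), Galnt10 (3.33), Nebl (2.97), Eya2 (3.06) and the granule protease gene Gzma (2.92). Dividing-cell genes stood among them, with Depdc1b at 3.45 and Cenpf, a kinetochore protein, at 2.95. The genes with the lowest upper bounds included Lag3 (-2.94), Ank3 (-2.95), the chemokines Ccl5 (-2.32) and Ccl4 (-2.26), Dgkg (-2.81), the nuclear receptor Nr4a2 (-2.28), Setbp1 (-2.02), Trps1 (-1.94), Mir155hg (-2.12) and Cd7 (-2.03).

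Genes of T cell exhaustion, the state of T cells under lasting antigen stimulation, were lower in PT-Cy. Of 22 members of the list fixed before the data were examined, 17 were at least 1.5-fold lower, 0 were 1.5-fold higher, and the median log2 ratio was -1.10, below all 10000 random lists matched on expression, whose central 95% ran from -0.20 to 0.23. Tox, a transcription factor of the exhausted state, had 5849.8 CPM in alloBMT and 1943 in PT-Cy, 3.01-fold lower (2.89 to 3.14). The inhibitory receptor genes Pdcd1 and Lag3 were 3.10-fold (2.49 to 3.90) and 7.70-fold lower (5.66 to 10.7), Tigit had a log2 ratio of -1.73 and Rgs16 of -2.12. Within the deposited CD4 cluster 2, which held 42 alloBMT and 238 PT-Cy cells, the list's median was -0.78, and within cluster 4, with 34 and 31 cells, it was -0.94 over the 12 members measured there.

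Genes of stem-like, memory and naive T cells were higher in PT-Cy. Of 22 measured members 15 were at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of 0.94, above all 10000 matched lists. Il7r, the interleukin-7 receptor, was 5.09-fold higher (4.26 to 6.10), the chromatin organiser Satb1 4.22-fold (3.65 to 4.89) and S1pr1, a receptor for exit into the circulation, 3.94-fold (2.79 to 5.59). Tcf7, the transcription factor of stem-like T cells, was 3.45-fold higher (2.59 to 4.61) from 84 and 121 UMIs. Within cluster 4 the list's median was 0.042, at percentile 56.4 of matched lists. Il7r had a log2 ratio of -0.41 there, given without an interval.

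Effector and cytotoxic genes moved apart. Of 24 measured members 15 were at least 1.5-fold lower and 5 at least 1.5-fold higher, with a median of -0.84, below all 10000 matched lists. Ccl5 and Ccl4 were 4.98-fold (4.71 to 5.27) and 4.79-fold lower (4.07 to 5.66), Klrc1 had a log2 ratio of -2.40, and Ifng, the gene of interferon gamma, was 2.84-fold lower (2.29 to 3.55). Gzma was 7.58-fold higher (5.66 to 10.3) and Gzmb 2.04-fold higher (1.82 to 2.28), both granule proteases of killer cells, while Gzmk had -0.22 (-0.46 to 0.018), and -0.35 (-0.59 to -0.11) with TMM scaling. The higher Cd8b1 share of PT-Cy stands beside these values. In cells with no Cd8b1 UMI, Gzma had a log2 ratio of 3.25, Gzmb of 0.86 and Gzmk of -0.61. That cut cannot free these values of CD8 cells. It took CD8 accessibility, relative to the CD8 set, from 32.5% to 28.2% in PT-Cy and from 21.3% to 11.4% in alloBMT.

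Genes of cell division were higher in PT-Cy. Of 22 members 18 were at least 1.5-fold higher and 0 lower, with a median of 1.95. Mki67, a marker of cycling cells, was 4.12-fold higher (3.72 to 4.58) and Cenpf 7.75-fold (6.27 to 9.65); the mitotic genes Ccnb1, Tpx2 and Cdk1 had log2 ratios of 2.60, 2.55 and 2.46. Within cluster 2 the median was -0.12 and Mki67 had -0.077. That cluster is itself marked by dividing-cell genes, with E2f7 and Ncapg2 among its leading genes. Its alloBMT cells had Mki67 at 866 CPM, against 136, 149 and 145 in alloBMT clusters 0, 1 and 3. A comparison inside it therefore cannot show whether division differed between the libraries. Within cluster 4 the median was 1.02 over the 9 members measured there, with Mki67 at 1.91.

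Genes of regulatory T cells (Treg) had a median of 0.82, with 8 of 14 at least 1.5-fold higher and 3 lower. Il2ra, a chain of the interleukin-2 receptor, was 5.92-fold higher (4.46 to 7.93) and Nrp1 6.65-fold (4.94 to 9.03), and Foxp3, the lineage factor, had a log2 ratio of 1.33 from 42 and 44 UMIs. Il10, a suppressive cytokine, was 4.61-fold lower (2.88 to 7.82). Within cluster 4, led by Dscam, Wls and Itgae, the list's median was -0.22, with Il2ra at -0.44 and Foxp3 at -0.22, and within cluster 2 it was 0.85, with Il2ra at 1.79. Of the costimulation and interleukin-18 receptor genes, Il18r1 had a log2 ratio of 1.37 and Il18rap of 1.05, while the list's median of 0.15 lay inside the range of matched lists.

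**Figure D1:**
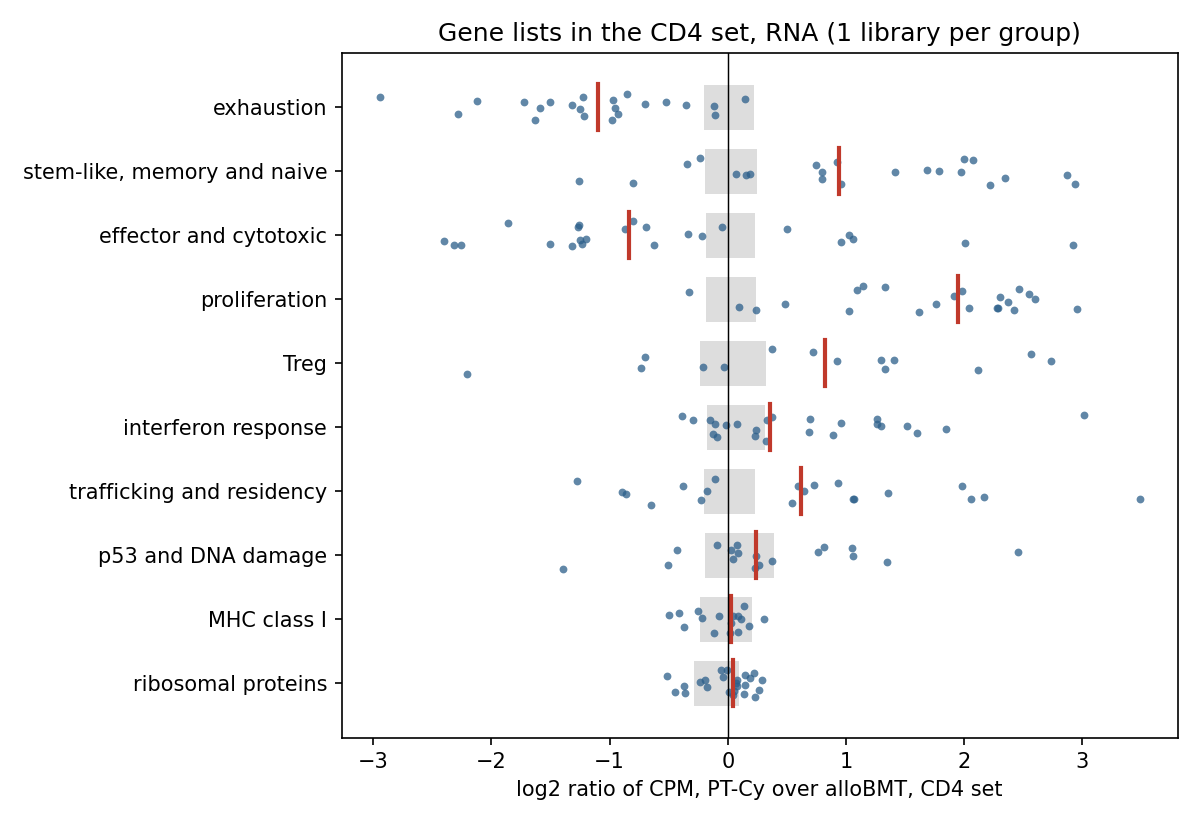
Each point is the log2 ratio of CPM (PT-Cy over alloBMT) of a gene with at least 20 UMIs in the CD4 set; red lines are list medians and grey bars the central 95% of medians of 10000 matched random lists. The exhaustion median lies at -1.10 and the proliferation median at 1.95, outside the grey bars, while MHC class I and ribosomal protein medians lie inside.

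Trafficking genes had a median of 0.62, with Itgb7 at 2.17 and Itga1 at 2.06, but of -0.082 in cells with no UMI of 5 proliferation markers, of which PT-Cy had 16. Interferon response genes had a median of 0.35 at percentile 98.9 of matched lists, with Bst2 at 1.60 and Ly6a at 1.52, but of -0.051 within cluster 2. The p53 and DNA damage list, which the drug given makes of interest, had a median of 0.23 at percentile 83.9. Zmat3 had 1.34, and Cdkn1a, with 77 and 67 UMIs over the whole CD4 set, had 1.06. Within clusters 2 and 4 Cdkn1a had -0.62 and -0.54. Ratios of single genes within clusters are given without intervals, so small ones can be counting error. MHC class I genes had a median of 0.023 and ribosomal protein genes of 0.047, and 0 members of either list passed 1.5-fold.

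Depth per cell differed, so shares of cells with a UMI were compared after each cell was thinned to 1981 UMIs, which left out 96 alloBMT and 25 PT-Cy cells. A Tcf7 UMI was found in 4.22% of alloBMT cells (2.95 to 5.82) and 17.4% of PT-Cy cells (13.0 to 22.5), an Il7r UMI in 5.90% and 34.0%, and an Il18r1 UMI in 12.3% and 38.2%. Tox was found in 97.6% and 75.3% of cells, Pdcd1 in 34.7% and 12.7%, Ifng in 31.8% and 13.5%. Mki67 was found in 20.7% and 63.7%, Gzma in 2.29% and 21.2%, and Gzmb in 31.0% and 51.0%. Of genes T cells lack, S100a9 was found in 1.93% and 8.49% and Hbb-bs in 20.4% and 52.1%. The PT-Cy share of Hbb-bs lies above those of Tcf7, Il7r, Il18r1, Gzma and Gzmb, whose own background was not measured. Foxp3 was found in 1.81% and 6.95% of cells, and most of its UMIs lay in cluster 4: 31 of 42 in alloBMT and 29 of 44 in PT-Cy, at 240.4 and 207 CPM. In PT-Cy cluster 2 it had 12.4 CPM from 13 UMIs, against 66.9 CPM for S100a9 there and 28.5 in PT-Cy cluster 4. Unthinned, the shares for Tcf7 were 6.59% and 28.2%, for Tox 98.6% and 84.9%, and for Mki67 27.4% and 77.8%.

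**Figure D2:**
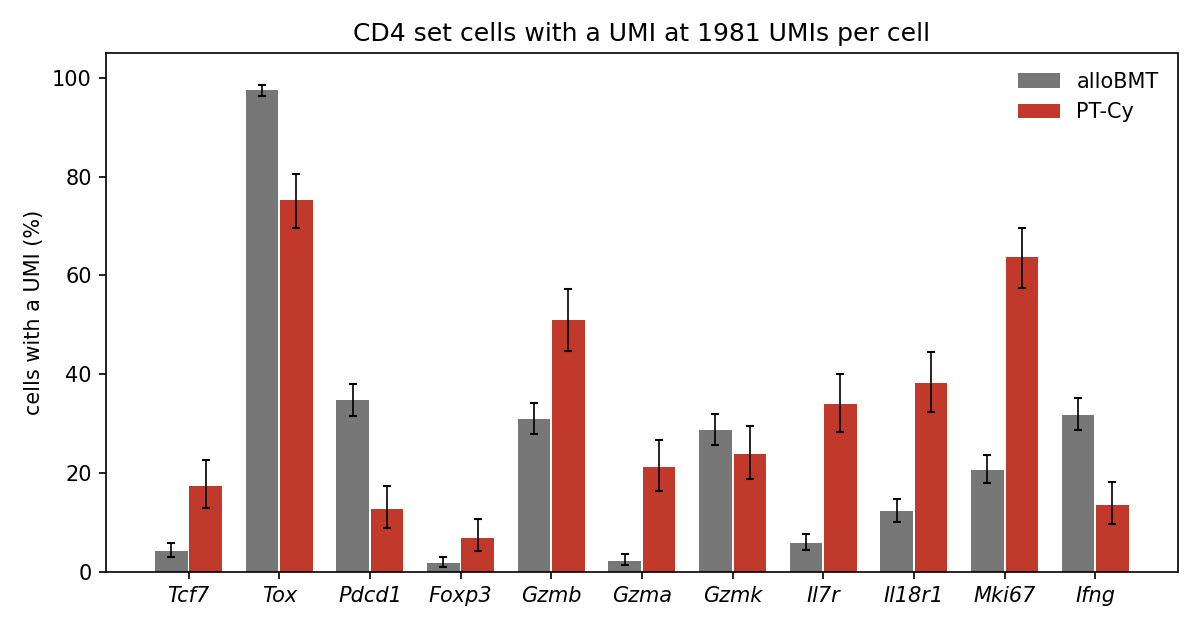
Share of CD4 set cells (%) with a UMI of each gene shown after thinning to 1981 UMIs per cell, alloBMT in grey and PT-Cy in red, with exact 95% binomial intervals as bars. Mki67 stands at 20.7% and 63.7%, and Tox at 97.6% and 75.3%.

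The deposited per-cell scores, for gene sets named stem-like and Tex, the latter read here as exhausted T cells, were compared as differences within each set. In the CD4 set the RNA stem-like score had a mean of -0.0473 in alloBMT (SD over cells 0.0946) and 0.0722 in PT-Cy (SD 0.119). The exhaustion score had means of 0.0134 and -0.0280. In the CD8 set the same scores had means of -0.00428 and 0.0636, and of 0.0263 and -0.0176. The accessibility scores of the CD4 set had means of 0.00944 and 0.0744 for stem-like and of 0.0368 and 0.0172 for exhausted, and those of the CD8 set of 0.0285 and 0.0815 and of 0.0558 and 0.0350. In the CD8 set 5.08% of PT-Cy cells lay above the alloBMT median of the RNA exhaustion score.

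Most of the deposited clusters separated by library. CD4 clusters 0 and 1 held 374 and 320 alloBMT cells and 4 and 0 PT-Cy cells, and 0 of 284 has an exact upper bound of 1.29%. CD4 cluster 2 held 42 and 238, cluster 3 156 and 11, and cluster 4 34 and 31 cells. Of the 8 CD8 clusters, clusters 0, 3 and 7 held 506, 297 and 191 alloBMT cells and 0, 1 and 1 PT-Cy cells, and cluster 5 held 30 and 189. A cluster mostly of 1 library can be that library rather than a cell type. The numbers of such clusters are therefore not given as changes in abundance. CD4 cluster 4 held cells of both libraries and most Foxp3 UMIs. It made up 3.67% of alloBMT CD4 cells (2.56 to 5.09) and 10.9% of PT-Cy CD4 cells (7.54 to 15.1). Dscam, its leading gene, had a log2 ratio of 3.28 over all CD4 cells and 0.82 within it. With 1 library per group, the difference in share was not tested.

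The second question is whether chromatin differs at the same genes. Over all T cells, 711 of 44801 peaks with at least 100 counts were at least 2-fold more open and 1652 at least 2-fold less open in PT-Cy. A simulation with 44697 peaks, drawn independently and so without the spread between cells, had 87 unchanged peaks past 2-fold. Of the 15192 peaks within 2 kb of an end of a protein-coding gene 112 were more open and 191 less open, and of the 29609 elsewhere 599 and 1461. Of 19971 peaks with at least 100 counts in the CD4 set, 763 were less open and 150 more open. In the CD8 set these were 1173 and 361 of 35872. The minimum is over both libraries, and alloBMT had 23580292 counts against 4656839, so peaks open mainly in alloBMT pass it more easily. The excess of less open peaks is therefore not read as a result. Over all T cells, a minimum of 20 counts gave 6805 peaks more open and 7969 less open, with more counting error. Counting each cell once per peak gave 463 and 1504. The more open peaks with the highest lower bounds were on chromosome 6 from 99387880 to 99389501 in Foxp1 (log2 ratio 2.49; 2.13 in CD4, 2.76 in CD8), on chromosome 3 from 115800424 to 115801886, 85.4 kb from S1pr1 (2.25), on chromosome 14 from 61056244 to 61057533, 9.39 kb from Tnfrsf19 (2.22), on chromosome 19 from 40267237 to 40267737 in Pdlim1 (2.29) and on chromosome 14 from 122013405 to 122013970 in Ubac2 (2.16). The less open peaks with the lowest upper bounds were in Pde4d on chromosome 13 from 109760964 to 109761830, with 194 counts in alloBMT and 0 in PT-Cy (upper bound of the ratio -3.36), in Il33 on chromosome 19 from 29959864 to 29961244 (-3.23), 6.82 kb from Htra3 on chromosome 5 from 35686637 to 35687572 (-2.87), in Ppm1h on chromosome 10 from 122774788 to 122775473 (-3.64, -5.94 to -2.08) and in Hps1 on chromosome 19 from 42770039 to 42771196 (-3.05). Coordinates are as in the deposited peak names, and the gene is the one the peak overlaps or, with a distance, the nearest one.

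Accessibility summed over the peaks at each gene differed in the direction of the RNA at several state genes of the CD4 set. Tox had a log2 ratio of -0.48 (-0.61 to -0.35), Pdcd1 of -0.55 (-0.78 to -0.33), Lag3 of -0.62 and Nr4a2 of -0.78. Il7r had 1.18 (0.70 to 1.65), Il18r1 0.74, Ccr7 0.74, Tcf7 0.47 (0.27 to 0.67) and Il2ra 0.67. Gzma and Gzmb, higher in RNA, had -0.093 (-0.71 to 0.48) and -0.070 (-0.50 to 0.34), not separable from 0 at this depth. The exhaustion list had a median of -0.21 and the effector list of -0.27, below all 10000 matched lists, and the stem-like list 0.45, above all of them. The Treg list, higher in RNA, had -0.17 at percentile 0.51, and 0.0013 when peaks within 10 kb were counted; 3 of 16 members were at least 1.5-fold higher and 1 lower. Foxp3 was among the higher, at 1.12 (0.35 to 1.85) from 50 and 24 counts. TMM scaling shifts the CD4 ratios by 0.20, which gave medians of -0.41, -0.47 and 0.25 for the exhaustion, effector and stem-like lists.

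In the CD8 set the stem-like list had a median of 0.22, above all 10000 matched lists, with Ccr7 at 0.55 and Il7r at 0.67. Pdcd1 had -0.37 (-0.50 to -0.23) and Lag3 -0.32, while Tox had -0.081 (-0.16 to 0.0015), and -0.17 (-0.25 to -0.086) with TMM scaling. The exhaustion and effector medians were -0.034 at percentile 26.1 and -0.027 at percentile 36.6 of matched lists, while the deposited accessibility score for exhausted cells differed by -0.516 SD over cells in CD8 and -0.518 SD in CD4. The difference between CD4 and CD8 was not tested.

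Across 6011 genes with at least 100 counts in both assays, the log2 ratios of RNA and accessibility in the CD4 set had a Pearson correlation of 0.370 (0.348 to 0.392) and a Spearman correlation of 0.279; genes are not independent replicates, and this interval treats them as if they were. Of 285 measured loci of the genes 2-fold higher in RNA, 204 had a ratio above 0, and of 159 loci of the genes 2-fold lower, 135 had a ratio below 0, beside 7684 of all 15127 loci above 0. With TMM scaling 126 of the 285 lay above 0, 150 of the 159 below 0, and 3695 of all loci above 0. The accessibility ratios of the CD4 and CD8 sets correlated at 0.441 over 12785 genes. Both sets come from the same libraries, and the CD4 set carried some signal of CD8 cells. The value therefore cannot show that the sets share a response.

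**Figure D3:**
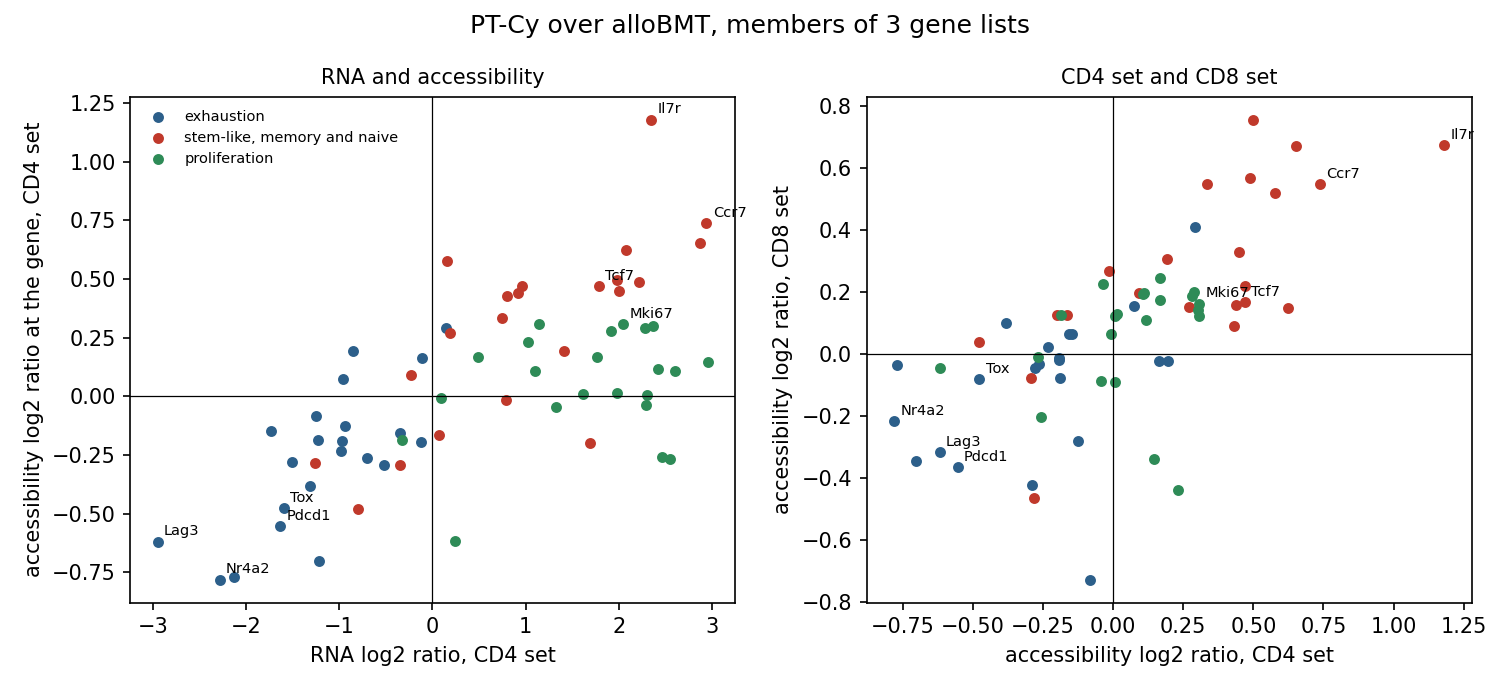
Log2 ratios (PT-Cy over alloBMT) of members of the exhaustion, stem-like and proliferation lists, RNA against accessibility at the gene in the CD4 set on the left and accessibility in the CD4 against the CD8 set on the right; each point is a gene with at least 20 counts in each set. Il7r lies at 2.35 in RNA and 1.18 in accessibility, and Lag3 at -2.94 and -0.62.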

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

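The settings by cluster, by Cd8b1 UMI in the list medians, by haemoglobin or neutrophil UMIs, by proliferation markers and, for the lists, without the cells with the most UMIs were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The motif results, the RNA results with CD4 and CD8 weighted equally and the gate on all T cells were not run, and no PT-Cy cell was left with no UMI of the proliferation list. Of 962 alternative values, 727 of the named genes, clusters and minor lists and 61 of the main results stayed within their interval or within 1.5 times; of 529 values of named RNA genes under scaling, per-cell means and 2 of the cell subsets 525 kept their sign, the others being Ctss, near 0. Signs were kept by 192 of 212 RNA list medians, 57 of 72 in CD4 ATAC and 36 of 48 in CD8 ATAC. A median is called reversed if its sign changed and its value in the main setting lay outside the central 95% of matched lists. The other lost signs were of medians inside that range. Within their own cell subset, the RNA medians called reversed lay inside the range of matched lists. The cause of the differences below was not tested unless the setting itself gives it.

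With a minimum of 20 counts, which tests more features, 912 genes were 2-fold higher and 474 lower, and 6805 peaks higher and 7969 lower; counting each cell once per peak gave 463 peaks higher. TMM scaling moved the RNA stem-like median to 0.81, the CD4 ATAC exhaustion, stem-like and effector medians to -0.41, 0.25 and -0.47, and those of CD8 to -0.12, 0.13 and -0.11. It took below 0 the ATAC medians of proliferation in CD4 (-0.088), immediate early genes in CD4 (-0.11) and p53 genes in CD8 (-0.011). Because it shifts all ratios of a set alike, the place of these lists among matched lists stays the same. Peaks within 10 kb reversed the CD4 ATAC medians of Treg (0.0013) and neutrophil genes (0.12). With at least 100 UMIs the RNA stem-like and effector medians were 0.80 and -1.20. Means in place of medians gave -0.54 for effector and 1.67 for proliferation genes.

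Cluster 2 alone gave RNA medians of -0.78 for exhaustion, 0.39 for stem-like and -0.63 for effector genes, and reversed proliferation (-0.12), interferon (-0.051) and sex-linked genes (-0.13). Cluster 4 alone gave -0.94 for exhaustion, 0.042 for stem-like and 1.02 for proliferation genes, and reversed Treg (-0.22) and sex-linked genes (-0.093). Cells with no Cd8b1 UMI gave 1.19 for stem-like genes in RNA and -0.49 for effector genes in CD4 ATAC. Without the 5% of cells with the most UMIs the proliferation median was 2.13. Cells with no UMI of the 5 proliferation markers, of which PT-Cy had 16, gave 1.30 for stem-like and 0.80 for proliferation genes, and reversed trafficking (-0.082) and glycolysis genes (-0.046). The CD4 share of alloBMT was 26.3% among cells with at least the median UMI count. Unthinned differences in share between PT-Cy and alloBMT were 21.6 points for Tcf7, -13.7 for Tox, 42.6 for Il7r and 50.4 for Mki67.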

Other observations

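The tests of clusters, of the marker genes of dividing cells, of the share of CD8 cells by accessibility and of blood cell transcripts were made after the results were seen. The preset list of NK and gamma delta T cell genes had a median of 0.85 in the CD4 set, inside the 95% range of matched lists (-0.52 to 0.89), with 4 of 7 measured members at least 1.5-fold higher and 2 lower, among them Tcrg-C2 at -1.01. Chosen after their values were seen, Zbtb16 had 21 UMIs in alloBMT and 72 in PT-Cy, Klrb1c 1 and 32, Cd163l1 1 and 13 and the cytokine gene Il22 1 and 15.

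Metabolic lists had medians somewhat above 0 in the CD4 set, with most members within 1.5-fold. These were 12 of 17 glycolysis, 15 of 20 nuclear oxidative phosphorylation and 11 of 13 mitochondrially encoded genes. Glycolysis genes had a median log2 ratio of 0.38, with Eno1 at 1.57 and Ldha at 0.98, nuclear genes of oxidative phosphorylation 0.34, with Cox6a1 at 1.04, and mitochondrially encoded genes 0.29, with mt-Co1 at 0.60, beside a median mitochondrial share of UMIs per cell of 3.69% in alloBMT and 4.75% in PT-Cy. In cells with no UMI of 5 proliferation markers, of which PT-Cy had 16, the glycolysis median was -0.046 and that of oxidative phosphorylation 0.24, at percentile 58.2 of matched lists. Helper cytokine and regulator genes had a median of 0.94 over 9 measured members, with Il12rb2 at 1.76 and Maf at -0.67. General T cell genes had a median of -0.23, with Cd247 at -1.04, Cd3g at -0.91 and Thy1 at 0.82. Of other cell types, the B cell list had a median of 2.23 over 6 members, with Cd74 at 2.10, the monocyte list 1.24, the erythroid list 2.20 and the neutrophil list 4.09 over 5 members each, or 4.61-fold and 17.1-fold (2.84-fold over 4 and 3.09-fold over 3 members without cells with many haemoglobin or neutrophil UMIs), and Xbp1, the 1 measured gene of the plasma cell list, 0.46. Immediate early genes had a median of -0.13 at percentile 8.85 of matched lists.

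Cycling genes were higher in PT-Cy, and 3 technical explanations were weighed. More UMIs per cell is argued against by the share of cells with an Mki67 UMI at 1 thinned depth, 43.0 percentage points higher in PT-Cy. Doublets among the cells with the most UMIs are argued against by a median of the proliferation list of 2.13 without those cells. The same cut left the median of the neutrophil list at 4.16 and of the erythroid list at 2.27. It thus did not remove RNA of other cells, and other doublets stay open. CD8 cells carried in the CD4 set stay open: in cells with no Cd8b1 UMI the median was 1.94, but leaving out the others took CD8 accessibility, relative to the CD8 set, from 32.5% to 28.2% in PT-Cy and from 21.3% to 11.4% in alloBMT, too little to decide. The drug, free RNA of cycling cells and other differences between the pools of mice also stay open and untested, since each group is 1 library.

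Exhaustion genes were lower in PT-Cy. CD8 cells in the CD4 set stay open. Cells with no Cd8b1 UMI (median -1.25) kept much of the CD8 accessibility. The lowest ratio that CD8 cells with no exhaustion transcripts could give was -0.98, at the highest share by the Cd8 loci (49.3%). That lies only just above the interval of the median of -1.10 (-1.27 to -0.998), which covers counting error only. The share takes carried cells to be as open at the Cd8 loci as the CD8 set, though the CD4 set was chosen without Cd8a UMIs. The Cd4 locus, at 93.5 CPM in alloBMT and 72.8 in PT-Cy, sets a looser limit (88.7%) and does not raise that share. In alloBMT, accessibility at the exhaustion list summed to 3800 CPM in the CD4 set and 3828 in the CD8 set. In PT-Cy these sums were 3196 and 3686. CD8 cells at such levels would not lower the summed accessibility of the CD4 set. RNA of the CD8 set was not analysed here, so for the RNA pattern this explanation stays open. Loss of whole deposited clusters, with no change inside those that remain, is argued against by a median nearest to 0 of -0.78 within clusters 2 and 4. Cluster 2 held 42 alloBMT and 238 PT-Cy cells, and the mix of cells inside a cluster can differ between libraries. A change in make-up within clusters therefore stays open. A larger share of dividing cells could not be tested as planned, because 0 PT-Cy cells had no UMI of the proliferation list; in cells with no UMI of 5 marker genes, 350 in alloBMT and 16 in PT-Cy, the median was -1.17. The drug, and any difference between the pools, may account for the pattern and cannot be separated with 1 library per group.

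Haemoglobin and neutrophil transcripts were higher in PT-Cy. A few blood cell nuclei or doublets do not account for all of it, since summed haemoglobin UMIs had a log2 ratio of 2.01, and still 1.28 (1.11 to 1.45) without the 7 alloBMT and 35 PT-Cy cells that held more than 5 haemoglobin or 2 neutrophil UMIs. Those cells held most of the neutrophil signal of PT-Cy: without them its UMIs of the neutrophil list fell from 346 to 93, and the log2 ratio from 3.02 to 1.79 (1.33 to 2.25). Free RNA may account for the rest: among the other PT-Cy cells haemoglobin stood at 511 CPM (464 to 560) in cluster 2 and 473 (365 to 603) in cluster 4, against 150 and 163 in alloBMT. The share of Hba-a1 in Hba-a1 plus Hbb-bs UMIs differed between those clusters by -6.26 percentage points (32.7% and 39.0%), with intervals too wide to decide, so free RNA stays open.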
